A study of Mus musculus with 9 samples.

How the data were processed

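Libraries were grouped by their titles into RNA_DKO, RNA_Wt, ATAC_DKO and ATAC_Wt, with 2 libraries each, and 1 Cdx2 ChIP library labelled Wt. Per the labels, DKO and Wt differ in a tag, vill (+) or vill (-), and share the Cdx1 null and floxed Cdx2 alleles. The submitters' processing notes name BWA, Bowtie2, fastp, MACS2, Salmon 1.3.0 and DESeq2, and the builds mm10 and GRCm38, without roles. The settings of each tool, the transposase read shift and the ChIP control are not given in the sources used here.

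The RNA files held estimated counts per Ensembl transcript, made by the authors with Salmon from single-end reads, per the file headers. Salmon's TPM values in the same files were scaled by the authors' run for length and depth, per the file headers. The gene table held a mean normalized count for each gene, a signal that the authors obtained by scaling counts between libraries, per the file headers. Its log2 fold changes were made by the authors as DKO over Wt, and fold over SE does not return the deposited p for most genes (1751 of 17511 matched within 0.01 in log10), so the folds appear to be shrunken. The p-values in that table were computed by the authors, and the deposited adjusted p equals the Benjamini-Hochberg adjustment of the deposited p. Peak files gave a fold enrichment ratio over local background that the authors' caller, MACS2 by the processing notes, wrote for each peak. Each peak's -log10 p and -log10 q and its score, a rounded multiple of -log10 q, are also the authors', per the file format. Peaks were called per library, as the peak names carry the library, per the file headers. The smallest -log10 q listed was 1.30 in ATAC and 1.54 in ChIP.

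Transcript counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, glmQLFit and glmQLFTest, Benjamini-Hochberg adjusted p under 0.05, no covariate). The gene-level test that had been planned was not run, because nothing used here pairs the transcript IDs with genes, and gene-level values are therefore the authors'. For the same reason no gene-level value per library, no left-out library and no replicate block can be given for a named gene or gene list. The common dispersion between libraries was 0.441. Tested on simulated data with 200 of 33591 transcripts changed at a dispersion of 0.05, the test recovered 100% of the 4-fold and 16-fold changes with 6 false calls. At the observed dispersion, over 32853 transcripts, it recovered 0% of the 4-fold and 14% of the 16-fold changes with 0 false calls. All simulated transcripts had the same dispersion, and far fewer changed than were called in the data. These rates therefore do not give the power of the test on the data. The replicates were compared first: the chi-square per degree of freedom between libraries of a group was 72.6 in DKO and 44.8 in Wt, well above sampling noise, so each library was counted as its own sample. The direction of the deposited table was checked on features of at least 50000 mean reads and a log2 change of at least 4 in size: 0 transcripts were higher and 4 lower in the transcript fit, and 0 genes higher and 3 lower in the authors' table.

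The 26 gene lists and the naming rule were fixed before the data were examined. The rule takes Cdx2, Cdx1, Trim31 and Nlrp3, the 8 genes highest and 8 lowest in log2 fold change past the threshold, at a mean of at least 4 CPM (83.2 normalized counts) and with a symbol that is not a model name, up to 3 members per list, and Cdx2 peaks near these genes. Its condition on overlap between libraries could not be applied, and a gene that the rule takes from the posterior Hox list is not reported here. Lists were tested with cameraPR of limma 3.58.1 (two-sided) on the signed z of the deposited p, with a correlation of 0.01 between genes. An estimated correlation needs values per library and gene, so a correlation of 0.05, ranks, the deposited log2 fold change as the statistic and genes with a mean of at least 50 normalized counts were tried in its place, the first 3 of these chosen after seeing the data. On simulated values for 17453 genes, 10 of 10 shifted lists and 0 of 30 others were called.

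Peak sets were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 on the assembled chromosomes, with an overlap of at least 1 bp. Random placement drew each Cdx2 peak 100 times on its own chromosome. Regions are unions of overlapping ATAC peaks, lost where both Wt lists and neither DKO list hold a peak, and gained in the opposite case. Bound and unbound regions were compared by a Mantel-Haenszel odds ratio over 10 deciles of mean rank of fold enrichment in Wt, which returned 3.01 for a true 3 over 40000 simulated regions. Genes were placed by the RefSeq annotation of GRCm38.p6, the same assembly as mm10. It was used here as gene spans without strand, so both ends of each span stand in for the planned transcription start. Of the 17511 genes, 15133 (86.4%) had a span. Genes near peaks were compared with the rest by Fisher's exact test (two-sided) and cameraPR. Intervals are 95% and cover counting error only, and ATAC and ChIP read depths are unknown here. No genome was used here, so the planned CDX motif count was not run.

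Alternatives were DESeq2 1.42.0 size factors and its Wald test, other filters, length-scaled counts, leaving out each library, a replicate block, a 2-fold threshold, stricter peaks (-log10 q of 5 or more), an equal number of peaks per library, overlap by 0.5 of a peak, windows of 1 kb and 50 kb, and regions away from gene ends. Odds ratios for genes near peaks were also matched on deciles of mean count, a choice made after seeing the data.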

Results

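The series held 9 libraries from mouse colon epithelial cells, which the labels describe as enriched from fresh colon with EDTA. RNA-seq measured transcript levels in 2 libraries labelled DKO and 2 labelled Wt, and ATAC-seq, which marks open chromatin by transposase insertion, was run on another 2 and 2. ChIP-seq of Cdx2, a homeobox transcription factor of the intestinal epithelium, came as 1 library without a replicate. By their strain labels, all libraries carried a Cdx1 null allele and a floxed Cdx2 allele, and those labelled DKO were also tagged vill (+), against vill (-) in Wt. The RNA and ATAC mice received tamoxifen for 6 days, whereas the ChIP sample carries an untreated tag. The RNA libraries held 21197446 and 20069555 estimated reads in DKO replicates 1 and 2, and 16403301 and 25494309 in Wt replicates 1 and 2. The ATAC lists held 40101 and 23961 peaks in DKO and 48163 and 53943 in Wt, and the Cdx2 list held 5179 peaks. No label says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

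The series design named Cdx2 binding, chromatin accessibility and the expression of Cdx2 targets, and its title named Trim31 and Nlrp3. Cdx2 itself was not called lower in the libraries labelled DKO. The authors' deposited table gave a log2 fold change of -0.27 (SE 0.21, adjusted p = 0.301) at a mean normalized count of 9263. A gene total cannot resolve a deleted exon, so this value neither shows nor excludes the deletion, and the groups are called by their labels throughout. Cdx1 (chromosome 18, 61018862 to 61036199, GRCm38), null by the labels in both groups, was measured at a mean of 2595 normalized counts and was lower in DKO by the authors' deposited table (log2 fold change -1.06, SE 0.23, adjusted p = 2.08e-05). The labels call the same libraries Wt and Cdx1 null, and these values do not settle which holds, so no difference between the groups can be assigned to Cdx2 alone rather than to Cdx1 and Cdx2 together. Trim31 (chromosome 17, 36898130 to 36910217), an E3 ubiquitin ligase of the TRIM family, was lower in the libraries labelled DKO, with a log2 fold change of -1.48 (SE 0.45, adjusted p = 0.00135) in the authors' deposited table, a level 2.79-fold higher in Wt. Nlrp3, the sensor of the inflammasome that processes interleukin-1 beta, had a log2 fold change of 1.88 (SE 1.78, adjusted p = 0.0578) at a mean of only 8.77 normalized counts in the authors' deposited table, which did not pass the threshold.

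Across the transcriptome, the goblet cell genes Clca1 and Ang4 were among those that fell furthest and Lcn2 and S100a9 among those that rose furthest. Clca1, a secreted goblet cell protein, fell by 10.99 on the log2 scale (SE 0.36) and Ang4, a secreted antimicrobial ribonuclease, fell by 11.95 (SE 0.42) in the authors' deposited table. Abca12, a lipid transporter, and Slc30a10, a manganese exporter, had log2 fold changes of -13.98 (SE 3.38) and -13.44 (SE 3.33) in the authors' deposited table. Cfd (-11.05), Grin3a (-10.91), the pseudogene Gvin-ps5 (-10.73) and Cnn1, a smooth muscle calponin (-9.06), completed the 8 lower genes that the naming rule took from the authors' deposited table. On the higher side the authors' deposited table held Lcn2, the siderophore-binding lipocalin, at a log2 fold change of 11.63 (SE 0.87) and a mean of 18347 normalized counts. S100a9 (12.79), Cyp2a5 (13.37), Fam83a (11.69), Fga (11.30), H2ac19 (10.99), the pseudogene Tpt1-ps3 (11.94) and 1 of 2 gene IDs named Pakap (11.25) also rose in the authors' deposited table. Their SEs ran near 3 or above except for Lcn2, so the sizes are loosely set. Cyp2a5, Ang4, H2ac19 and both pseudogenes have close copies elsewhere in the genome among which reads could be split.

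In all, the authors' deposited table called 3231 genes higher and 3211 lower in the libraries labelled DKO at an adjusted p under 0.05, of 17511 genes, with a median log2 fold change of -0.02. At least 2-fold changes numbered 1925 higher and 2309 lower in the authors' deposited table. Over its genes with a mean of 50 or more normalized counts, with p readjusted, the authors' deposited table gave 3078 higher and 2434 lower. Markers of stroma, muscle and endothelium moved with the genotype labels, with a median log2 fold change of -4.51 over 20 genes in the authors' deposited table, and this value stands beside every gene group below.

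Single transcripts were tested from the deposited estimated counts, which carry transcript IDs and no gene names. The Wt pair and the DKO pair correlated at 0.904 and 0.882 (Pearson r across 21170 transcripts, which are not independent replicates), against 0.666 to 0.687 between the groups. The quasi-likelihood test of edgeR called 1910 transcripts higher and 1671 lower in DKO, of 35302 tested, at a Benjamini-Hochberg adjusted p under 0.05. ENSMUST00000169032.7 was measured at 424 and 342 CPM in the DKO libraries and at 0 in both Wt libraries, at least 5347-fold higher against a floor of 3 reads over the group. ENSMUST00000051122.6 was measured at 565 and 455 CPM in Wt and 0 in both DKO libraries, at least 7018-fold lower. These folds belong to single transcripts and not to genes. An estimate of 0 can also come from how reads were assigned among transcripts of 1 gene, which was not tested. The smallest adjusted p with all 4 libraries was 0.0330, close to the threshold. Leaving out any 1 of them gave 0 calls in edgeR, while 0 of the 3581 calls changed sign, with 8428 to 10554 transcripts at an unadjusted p under 0.05. The 3581 calls were chosen on these same libraries, so a kept sign was likely in advance. The Wald test of DESeq2 on all 4 called 5096 higher and 4595 lower. In 68.2% of transcripts the libraries of both groups did not overlap, where chance gives 33.3%.

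Genes of intestinal epithelial identity fell in the libraries labelled DKO. Of the 22 measured, the authors' deposited table called 15 lower and 1 higher (16 and 1 adjusted over the list alone), with Isx, a homeobox factor of the intestine, at -5.76 (SE 0.32), the alkaline phosphatase Alpi at -5.71 (SE 0.47) and the fatty acid binding protein Fabp2 at -4.14 (SE 0.30). Goblet cell genes fell as a group, 16 of 19 lower and 0 higher in the authors' deposited table (17 lower adjusted over the list alone), including the main intestinal mucin Muc2 at -4.95 (SE 0.20). Absorptive colonocyte genes were lower in 13 and higher in 5 of 22 by the authors' deposited table (the same counts adjusted over the list alone), with the bile acid transporter subunit Slc51a at -5.48 (SE 0.31) and the mucin Muc3 at -2.91 (SE 0.24), but the sodium channel subunit Scnn1b at 2.76 (SE 0.46). Drug metabolism genes were lower in 11 and higher in 3 of 25 by the authors' deposited table (the same counts adjusted over the list alone), with Cyp2c55 at -5.01 (SE 0.28), Ces2a at -3.62 (SE 0.26) and Gsta4 at 3.33 (SE 0.26). The competitive set test cameraPR gave adjusted p = 1.78e-09 for identity, 2.51e-39 for goblet cells, 0.000591 for absorptive colonocytes and 0.000147 for drug metabolism. With a correlation of 0.05 between genes in place of 0.01 the adjusted p values were 8.90e-06, 1.40e-24, 0.0116 and 0.00751. The absorptive list passed neither the rank form (adjusted p = 0.0765) nor the log2 form (adjusted p = 0.142) of the test. The log2 form also ended the drug metabolism call (adjusted p = 0.197).

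Gastric epithelial genes rose together. The authors' deposited table called 10 of 12 higher and 0 lower (the same counts adjusted over the list alone), with a median log2 fold change of 5.38, led by the trefoil factor Tff1 at 10.41 (SE 0.86) and the gastrokines Gkn2 at 9.34 (SE 2.86) and Gkn1 at 7.57 (SE 2.87). Gkn1 had a mean of 21.7 normalized counts in the authors' deposited table. The set test gave adjusted p = 3.02e-06, and 0.000129 with a correlation of 0.05. The list names 19 genes, and those not measured are left out of the counts, the median and the test. A gene near silent in Wt may be measured mainly where it rises, so the direction may partly follow from which members were measured. Stratified squamous genes showed no common direction in the authors' deposited table, with 2 of 8 higher and 2 lower (the same counts adjusted over the list alone), among them Krt4 at 7.12 (SE 1.53), Ivl at 5.60 (SE 3.10) and Krt17 at -3.07 (SE 1.48), and an adjusted set p = 0.837. Ivl and Krt17 had means of only 9.77 and 12.7 normalized counts in the authors' deposited table. The median of the squamous list was -0.06, while its mean, 0.96, and the test pointed up. Small-intestinal enterocyte genes were split, 4 higher and 4 lower of 15 in the authors' deposited table (the same counts adjusted over the list alone), with the lipid transfer protein Mttp at 4.66 (SE 0.35), Fabp1 at 2.40 (SE 0.70) and sucrase-isomaltase, Sis, at -9.84 (SE 2.97), and the set test did not pass (adjusted p = 0.569). Its median was 0.02 and its test pointed up, while its mean was -0.24.

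**Figure D1:**
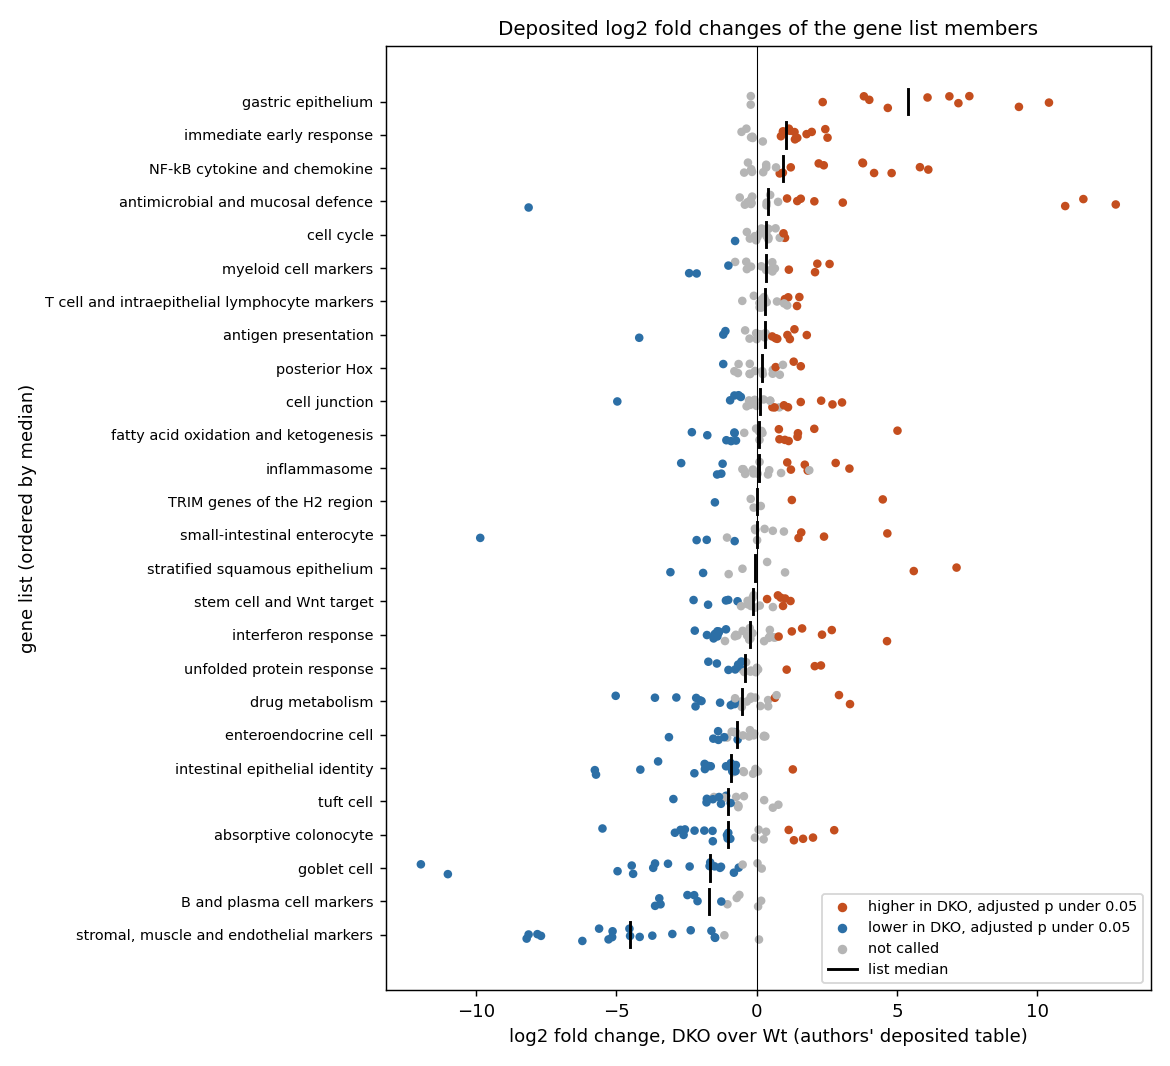
Log2 fold change of DKO over Wt from the authors' deposited table (horizontal axis) for each measured member of the 26 gene lists (vertical axis), coloured by the deposited call at an adjusted p under 0.05, with black bars at list medians. Stromal, muscle and endothelial markers lie lowest with a median of -4.51 and gastric epithelial genes highest with a median of 5.38.

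Inflammasome genes had no common direction in the libraries labelled DKO. Of 22 measured, the authors' deposited table called 6 higher and 4 lower (7 and 4 adjusted over the list alone). Among them the authors' deposited table held the cytokine genes Il1b at 2.82 (SE 0.63) and Il1a at 3.31 (SE 2.29). Il1a had a mean of only 8.51 normalized counts in the authors' deposited table. The epithelial sensor Nlrp6 was at -2.68 (SE 0.19, adjusted p = 6.29e-42) in the authors' deposited table. The set test gave adjusted p = 0.910. Among the 6 TRIM genes of the H2 region, the authors' deposited table called 2 higher and 1 lower (the same counts adjusted over the list alone), Trim10 at 4.49 (SE 1.51), Trim15 at 1.26 (SE 0.32) and Trim31 as the lower one, with a set p of 0.824 after adjustment.

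NF-kB and immediate early genes were higher. Of 19 NF-kB cytokine and chemokine genes, 11 were higher and 0 lower in the authors' deposited table (the same counts adjusted over the list alone), with the neutrophil attractants Cxcl2 at 5.82 (SE 1.00) and Cxcl5 at 4.81 (SE 1.54) and the growth factor Csf3 at 6.11 (SE 3.00). Immediate early genes followed with 12 of 18 higher and 0 lower in the authors' deposited table (the same counts adjusted over the list alone), among them Ier3 at 2.53 (SE 0.34), Egr1 at 2.45 (SE 0.28) and Fosl1 at 1.96 (SE 0.50). Csf3 had a mean of only 11.7 normalized counts in the authors' deposited table. The NF-kB and immediate early sets both passed the set test (adjusted p = 0.000755 and 0.000143, and 0.0116 and 0.00415 with a correlation of 0.05). Antimicrobial and mucosal defence genes were higher in 8 and lower in 1 of 20 by the authors' deposited table (9 and 1 adjusted over the list alone), with S100a9 and Lcn2 above and S100a8 at 10.99 (SE 2.13). The lower member, named after its values were seen, was the intelectin gene Itln1 at -8.11 (SE 1.77) in the authors' deposited table, and the median of the list was 0.42. The adjusted set p of that list was 0.0149, and the call was lost with a correlation of 0.05 (adjusted p = 0.0802), in the rank form (adjusted p = 0.0587) and over genes with a mean of 50 or more normalized counts (adjusted p = 0.0575). Interferon response genes went both ways in the authors' deposited table, 6 higher and 9 lower of 32 (6 and 11 adjusted over the list alone), with the chemokines Cxcl9 at 4.64 (SE 0.61) and Cxcl10 at 2.33 (SE 0.69) and the GTPase Iigp1 at 2.68 (SE 0.66). The median of the list was -0.25 and its set test did not pass (adjusted p = 0.584). Antigen presentation genes were higher in 7 and lower in 3 of 19 by the authors' deposited table (the same counts adjusted over the list alone), including H2-DMb1 at 1.79 (SE 0.45), Nlrc5 at 1.35 (SE 0.55) and the intestinal class Ib gene H2-T3 at -4.18 (SE 0.50). That set did not pass (adjusted p = 0.790).

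Among the remaining epithelial lists none passed the set test in the main form. Enteroendocrine genes were lower in 7 and higher in 0 of 18 by the authors' deposited table (the same counts adjusted over the list alone), with somatostatin, Sst, at -3.12 (SE 0.38), Scg3 at -1.54 (SE 0.60) and Cck at -1.37 (SE 0.77). Tuft cell genes were lower in 8 and higher in 0 of 18 by the authors' deposited table (the same counts adjusted over the list alone), with the cation channel Trpm5 at -1.77 (SE 0.34), Alox5 at -1.78 (SE 0.43) and Chat at -2.96 (SE 1.92). Chat had a mean of only 10.6 normalized counts in the authors' deposited table. The adjusted set p values of the enteroendocrine and tuft lists were 0.0952 and 0.0511, and 0.0251 and 0.00722 in the rank form. Stem cell and Wnt target genes stood at 6 higher and 5 lower of 20 in the authors' deposited table (7 and 5 adjusted over the list alone), with Ascl2 at -2.24 (SE 0.50), Cdca7 at -1.73 (SE 0.38) and Msi1 at 1.21 (SE 0.56). Cell cycle genes stood at 4 higher and 1 lower of 23 (2 and 1 adjusted over the list alone) in the authors' deposited table, with Ccnb1 at 1.01 (SE 0.37), Bub1 at 0.99 (SE 0.45) and Rrm2 at 0.96 (SE 0.41). Cell junction genes stood at 8 higher and 5 lower of 24 in the authors' deposited table (the same counts adjusted over the list alone), where the pore-forming claudin Cldn2 was at 3.04 (SE 0.34), Cgnl1 at 2.70 (SE 0.28) and Cldn15 at -4.96 (SE 0.22). The posterior Hox list stood at 3 higher and 1 lower of 17 in the authors' deposited table. The counts were the same adjusted over the list alone, and its members are not all Hox genes. In the authors' deposited table Hoxa9 was at 1.57 (SE 0.33) and Hoxa10 at 1.32 (SE 0.32). Fatty acid oxidation and ketogenesis genes stood at 8 higher and 7 lower of 21 in the authors' deposited table (the same counts adjusted over the list alone), with Angptl4 at 5.02 (SE 0.49), Pdk4 at 2.05 (SE 0.99) and Cyp4f14 at -2.30 (SE 0.40). Unfolded protein response genes stood at 3 higher and 7 lower of 18 in the authors' deposited table (the same counts adjusted over the list alone), with Herpud1 at 2.29 (SE 0.19), Trib3 at 2.07 (SE 0.63) and Ddit3 at -1.72 (SE 0.39). The adjusted set p values of these 6 lists were 0.904, 0.372, 0.552, 0.689, 0.904 and 0.817 in that order.

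Markers of other cell types moved apart. Stromal, muscle and endothelial markers were lower in 18 and higher in 0 of 20 in the authors' deposited table (the same counts adjusted over the list alone), led by the smooth muscle genes Tagln at -8.18 (SE 1.33), Acta2 at -8.11 (SE 0.35) and Myh11 at -7.80 (SE 0.42). The list passed the set test (adjusted p = 2.74e-30). B and plasma cell markers were lower in 7 and higher in 0 of 12 (8 and 0 adjusted over the list alone), with Jchain at -3.61 (SE 0.27), Igha at -3.46 (SE 0.34) and Igkc at -3.42 (SE 0.34) in the authors' deposited table. Their set test also passed (adjusted p = 0.000143). T cell and intraepithelial lymphocyte markers were higher in 4 and lower in 0 of 17 in the authors' deposited table (3 and 0 adjusted over the list alone), with Cd3d at 1.52 (SE 0.91), Gzma at 1.44 (SE 0.59) and Cd7 at 1.13 (SE 0.40). The adjusted set p was 0.315. Myeloid cell markers were higher in 4 and lower in 3 of 17 in the authors' deposited table (4 and 4 adjusted over the list alone), with Csf3r at 2.60 (SE 0.90), Cd14 at 2.16 (SE 0.20) and the complement gene C1qa at -2.40 (SE 0.33). Here the adjusted set p was 0.837. Of the 26 lists, 10 passed the set test, and 9 did with a correlation of 0.05.

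Cdx2 ChIP peaks mark enrichment that the authors' caller listed in the sample labelled Wt. With 1 library and no motif count, whether each peak is a site of Cdx2 binding was not tested. Regions called bound below are those that overlap a listed peak. Of the peaks on assembled chromosomes, 5100 in number, 13.9% lay within 1 kb of a gene end and 58.6% overlapped a gene span, with a median fold enrichment of 5.59 as the authors' caller gave it. At Trim31 a Cdx2 peak at 36897066 to 36897416 on chromosome 17 lay 714 bp before the start of the gene span (fold enrichment 5.95), and it overlapped an ATAC peak in both Wt lists and in neither DKO list. A weaker peak at 36922581 to 36922785 lay 12364 bp past the other end (fold enrichment 4.18) and overlapped no ATAC peak in any list. Cdx1 had a peak 3295 bp past its span end, at 61039494 to 61039732 on chromosome 18 (fold enrichment 4.75), outside the ATAC peaks of every list. Within 50 kb of Cdx2 and Nlrp3, and of the lower genes Cfd, Grin3a and Cnn1, the list held no Cdx2 peak. Abca12 carried a peak inside its span (chromosome 1, 71373014 to 71373452, fold enrichment 13.1). Ang4 had a peak 20568 bp past its span end (chromosome 14, 51794158 to 51794467, fold enrichment 9.89). Clca1 had a peak 11167 bp before its span start (chromosome 3, 144993048 to 144993370, fold enrichment 8.95). For Slc30a10 a peak lay 14981 bp past its span end (chromosome 1, 185483743 to 185484011, fold enrichment 4.63). Of these 4, the Clca1 peak overlapped an ATAC peak, in Wt replicate 2 alone. Spans were used without strand, so before and past refer to coordinates and not to the direction of transcription.

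**Figure D2:**
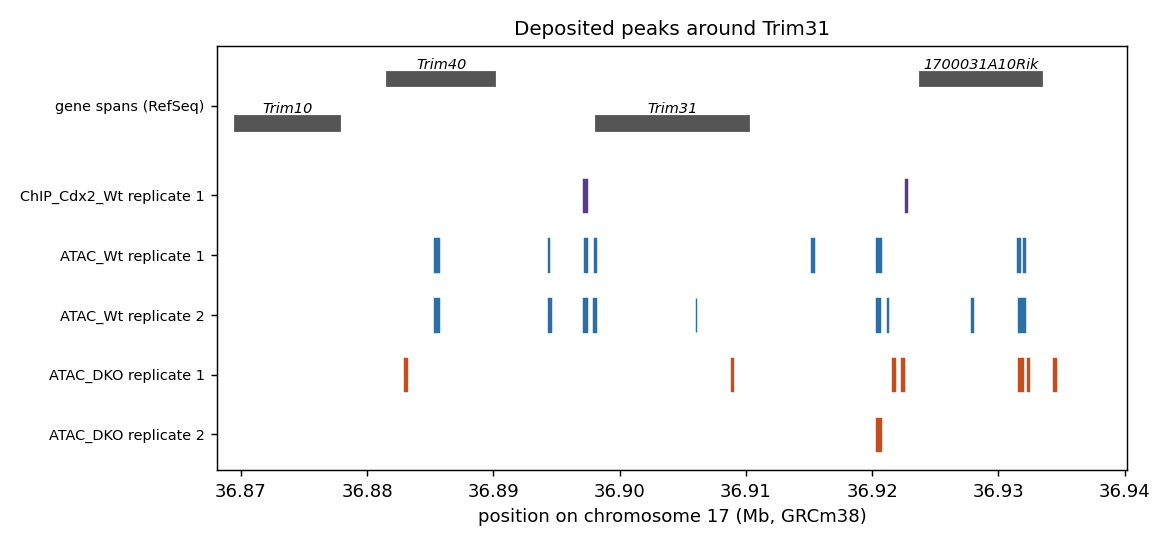
Deposited Cdx2 and ATAC peaks (boxes, 1 row per library) and RefSeq gene spans (grey) along chromosome 17 around Trim31, position in Mb (GRCm38). The Cdx2 peak 714 bp before the Trim31 span coincides with a peak in both Wt ATAC lists and in neither list labelled DKO.

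The 5 Cdx2 peaks of highest fold enrichment lay inside Abca8b (chromosome 11, 109933191 to 109933589, 20.3), Wwox (chromosome 8, 114505332 to 114505686, 19.3), Dync1i1 (chromosome 6, 5794169 to 5794510, 17.3) and Eri3 (chromosome 4, 117630363 to 117630714, 17.2), and 19299 bp from the lncRNA gene Gm38661 (chromosome 9, 121547456 to 121547850, 19.0). Among them the Dync1i1 peak alone overlapped an ATAC peak, in both Wt lists.

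A smaller share of Cdx2 peaks lay in listed open chromatin in the libraries labelled DKO than in Wt, where fewer than 0.5 of them did. In Wt replicates 1 and 2, 39.1% (95% Wilson interval 37.8 to 40.4%) and 41.1% (39.7 to 42.4%) of the 5100 Cdx2 peaks overlapped an ATAC peak by at least 1 bp. In DKO replicates 1 and 2 the shares were 2.12% (1.76 to 2.55%) and 4.76% (4.21 to 5.38%). Cdx2 peaks placed at random on the same chromosomes overlapped at 0.942% and 1.08% in Wt and at 0.776% and 0.529% in DKO. The group means were 40.1% ± 1.39 (SD, n = 2) and 3.44% ± 1.87 (SD, n = 2), an 11.6-fold difference with an exact permutation p of 0.333 (two-sided), the smallest that 2 against 2 libraries allow. The ratio was 18.9 without DKO replicate 2, 8.41 without DKO replicate 1 and 21.8 with ATAC peaks of -log10 q of 5 or more. The DKO lists were also weaker throughout, with 15.7% and 17.4% of peaks at a -log10 q of 5 or more, against 48.5% and 51.6% in Wt.

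**Figure D3:**
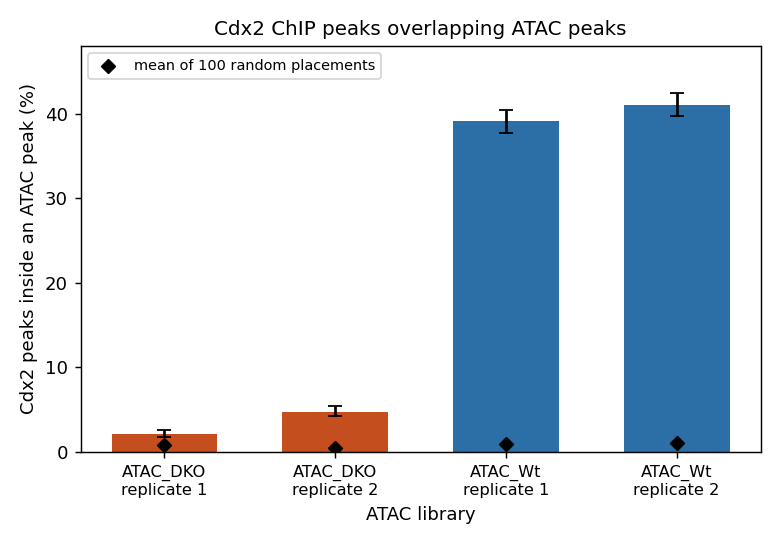
Percent of the 5100 Cdx2 peaks overlapping an ATAC peak in each ATAC library (bars, with 95% Wilson intervals) and the mean over 100 random placements (diamonds). Both Wt libraries stand near 40%, against 2.12% and 4.76% in the libraries labelled DKO.

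Regions open in both Wt libraries were mostly missing from the lists labelled DKO. Of 33634 such regions, 25304 (75.2%) had no peak in either DKO list, 4558 had one in a single DKO list and 3772 in both. Regions with a Cdx2 peak were missing more often than those without, 1548 of 1824 (84.9%, 95% Wilson interval 83.2 to 86.4%) against 74.7% (74.2 to 75.2%) of 31810. Matched on strength in Wt by decile, the Mantel-Haenszel odds ratio of loss was 2.61 (95% interval 2.25 to 3.02, counting error over regions, which are not replicates). Over 1 kb from gene ends, 91.8% of 1392 regions with a Cdx2 peak were missing, against 89.3% of 18280 without, so the shares were close. The odds ratio there was 1.72 (1.40 to 2.12). Over all regions with -log10 q of 5 or more it was 1.52 (1.24 to 1.88). Within 1 kb of gene ends it was 1.98 (1.58 to 2.49), with 62.5% of regions with a Cdx2 peak and 54.9% of those without missing. Matched on strength and on gene-end class it was 1.82 (1.56 to 2.12), and 2.21 (1.87 to 2.61) matched on width as well. Kept regions lay within 1 kb of a gene end in 80.2% of cases and lost ones in 30.4%. The lost and gained regions rest on DKO lists that shared less than the Wt lists did. Of the peaks of DKO replicates 1 and 2, 25.8% and 41.8% overlapped a peak of the other, against 73.3% and 64.1% in Wt, and 36.2% and 38.5% of the DKO replicate 2 peaks overlapped a peak of Wt replicates 1 and 2. For DKO replicate 1 these shares were 14.1% and 15.4%. In the opposite direction, 5305 regions were listed in both DKO libraries and neither Wt library, 9.01% of them within 1 kb of a gene end, and 5 of them carried a Cdx2 peak. The loss reached genes that were not called changed. Of 922 genes with a mean of at least 1000 normalized counts and an adjusted p of at least 0.5 in the authors' deposited table, 90.5% and 91.5% had a peak within 1 kb of a gene end in Wt, but 30.8% and 48.3% in DKO replicates 1 and 2. Of 840 genes of that mean called lower, the shares were 83.2% and 85.0% in Wt and 21.9% and 35.8% in DKO. The missing peak at Trim31, a gene called lower at a smaller mean, is to be read beside these shares.

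**Figure D4:**
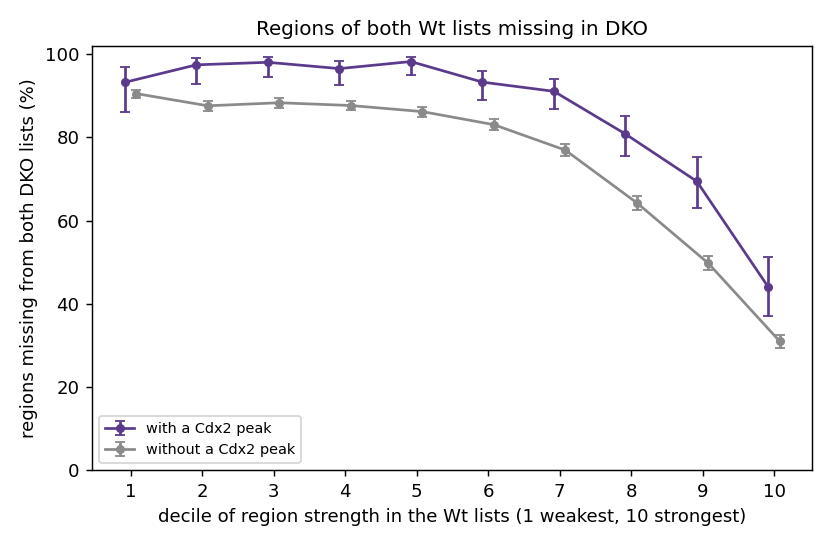
Percent of regions listed in both Wt ATAC libraries that have no peak in either library labelled DKO (vertical axis), by decile of region strength in Wt (horizontal axis), for regions with and without a Cdx2 peak, with 95% Wilson intervals over regions. In the strongest decile 44.0% of bound and 31.0% of unbound regions were missing. Distance from gene ends is not accounted for.

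Genes near Cdx2 peaks were called lower more often than other genes. Of 2075 genes with a Cdx2 peak within 10 kb of a gene end, 526 (25.3%) were lower in the authors' deposited table, against 18.6% of the other 13058 (odds ratio 1.48, 95% interval 1.33 to 1.65, Fisher's exact p = 3.41e-12). They included Trim31, Isx, Fabp2, Nlrp6, Cyp2c55, Muc3, Abca12 and Cdx1. The odds ratio of lower genes was 1.29 at 1 kb, 1.32 at 50 kb and 1.22 for Cdx2 peaks in regions accessible in both Wt libraries. With Cdx2 peaks of -log10 q of 5 or more it was 1.54. Higher genes were rarer near Cdx2 peaks, 18.1% against 20.9% by the authors' deposited table (odds ratio 0.836, 0.742 to 0.942, Fisher's exact p = 0.00310), though Cxcl9, Cd14, Hoxa9, Hoxa10 and Fosl1 were among them. This call was lost at 1 kb (0.818), at 50 kb (0.947) and for Cdx2 peaks in regions accessible in both Wt libraries (0.893), and kept in each of these when matched on mean count (0.668, 0.806 and 0.745). The set test over the genes near Cdx2 peaks gave p = 0.0478 toward lower, and 0.366 with a correlation of 0.05, so its call rests on the correlation assumed. Their median log2 fold change was -0.09 against 0.00 for the rest in the authors' deposited table, a small shift of the whole set.

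Near lost regions, higher genes were rarer. A lost region is by definition open in both Wt libraries. Comparing genes near lost regions with all other genes therefore does not separate loss from being open in Wt. By the authors' deposited table the odds ratio of being called higher was 0.874 (95% interval 0.805 to 0.948, Fisher's exact p = 0.00136). Matched on mean count it was 0.679 (0.623 to 0.740), and within 1 kb it was 0.710 unmatched and 0.577 matched. Unmatched, it turned to 1.15 at 50 kb and 1.06 with -log10 q of 5 or more, where the matched values were 0.758 and 0.697. The unmatched call was lost without DKO replicate 2 (0.939), Wt replicate 1 (0.940) or Wt replicate 2 (0.929). Of 9783 genes with a lost region within 10 kb, the odds ratio of being called lower in the authors' deposited table was 1.12 (95% interval 1.03 to 1.22, Fisher's exact p = 0.0101), and it turned to 0.812 (0.746 to 0.883) with ATAC peaks of -log10 q of 5 or more. It was 0.919 at 50 kb and 0.965 (0.880 to 1.06) without DKO replicate 2. Genes with a lost region but no Cdx2 peak within 10 kb had an odds ratio of being called lower of 0.923 (0.852 to 1.00), or 0.913 (0.841 to 0.990) matched on mean count. The comparison was with all other genes, which include every gene near a Cdx2 peak, so these ratios do not isolate the lost region. Of these genes 19.0% were called lower, against 18.6% of all genes without a Cdx2 peak, which include them. With both a lost region and a Cdx2 peak the odds ratio against all other genes was 1.54 (1.37 to 1.74), and 1.54 (1.37 to 1.74) matched. Near gained regions the odds ratio was 1.17 (1.02 to 1.34) for lower genes over 1371 genes, a call lost at 1 kb, at 50 kb and with stricter ATAC peaks. For higher genes it was 0.886 (0.769 to 1.02), which passed the test only without DKO replicate 1 (0.837), DKO replicate 2 (0.919) or Wt replicate 2 (0.863). The set test cameraPR gave p = 0.655 near lost regions (n = 9783 genes). It gave p = 0.514 near gained regions (n = 1371 genes).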

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

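The T cell test was chosen after its result was seen, and the second stromal list was chosen after the first list, Cnn1 and the collagens had been seen but before its own values were. A first test, the share of the first list at -1 or below, was computed, judged circular and replaced by that second list. The matching on expression and the correlation of 0.05 were added after seeing the data, and the remaining tests were chosen before their results were seen. The Cdx2 list held 79 peaks on unplaced contigs and the mitochondrial chromosome, 7 of them mitochondrial, and none of the comparisons used them. The 4 ATAC lists held 0 such peaks.

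Stromal, muscle and endothelial markers were lower in the RNA libraries labelled DKO. Fewer cells of every other kind in those preparations is argued against by the T cell and intraepithelial lymphocyte markers, whose median log2 fold change was 0.30 in the authors' deposited table. Fewer stromal and muscle cells should lower other markers of these cells too. A second list held 20 smooth muscle, fibroblast and endothelial genes, none of them in another list. Of these, 90% had a log2 fold change of -1 or below in the authors' deposited table, the exceptions being Hspb6 (-0.16) and Egfl7 (-0.74). The second list marks the same cell types in the same libraries as the first, so its fall was likely in advance. The second list also cannot tell fewer cells from lower expression per cell. Its most abundant genes, Mylk, Actg2 and Tpm2, at means of 1644, 1496 and 1451 normalized counts, stood at -1.27, -8.41 and -4.79 in the authors' deposited table. Fewer of these cells, lower expression per cell, a difference in what EDTA released and a difference in the tissue all stay open, since preparation and genotype label go together.

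Most regions open in Wt were missing from the ATAC lists labelled DKO. A shorter list in DKO is argued against, since with 23961 peaks taken from each library the Wt mean of Cdx2 peaks inside ATAC peaks was still 8.53 times the DKO mean. Lower signal over background in the DKO libraries stays open: among highly expressed genes not called changed, the lowest Wt share with a peak near a gene end lay 42.2 percentage points above the highest DKO share. A dependence of Cdx2-bound regions on Cdx2, alone or together with Cdx1, also stays open. The strength-matched odds ratio of loss was 1.72 away from gene ends, with its interval above 1. The shares missing there were close, 91.8% of bound and 89.3% of unbound regions. The general loss and the added loss at bound regions could both be present, and read depth and background were not measured here.

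Cdx2 transcript level was not called different between the groups by the authors' deposited table. If Cdx2 function had been intact in the mice labelled DKO, genes near Cdx2 peaks should have been called lower no more often than other genes of like expression. The lower bound of that matched odds ratio was 1.34, so they were called lower more often. This does not decide whether Cdx2 function was intact. Genes near Cdx2 peaks may be lower for reasons other than Cdx2, a loss of Cdx1 in the mice labelled DKO alone among them. The set test over the same genes was weaker (p = 0.366 with a correlation of 0.05 between genes). A transcript that is still made but lacks the deleted exon was not tested.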

How the results depend on the processing

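Choices other than the correlation of 0.05, ranks, the log2 statistic, protein-coding genes only, expression matching alone or with another choice, the strata by gene-end class and width, and regions near gene ends were fixed before the data were examined. In the authors' table, 2-fold changes left 1925 higher genes. For transcripts, edgeR called 111 higher and 111 lower without a filter, more transcripts being tested, and DESeq2's Wald test called 5096 higher and 4595 lower, including all 3581 main calls. Leaving out each library gave 0 to 0 calls in both directions in edgeR (8428 to 10554 at an unadjusted p under 0.05), with 0 of the 3581 calls changing sign, fewer samples and no spread within an arm of 1 library, whose variation is taken from the other group. A kept sign was likely in advance, since the calls were chosen on the same libraries. Replicate numbers did not pair the libraries (deviation correlation -0.0146), and the replicate block gave 0 higher and 0 lower transcripts with 8221 at an unadjusted p under 0.05. The Wt minus DKO difference in Cdx2 peaks inside ATAC peaks, 36.6 percentage points, moved to 26.3 with -log10 q of 5 or more, 23.3 with equal numbers of peaks and 33.6 with an overlap of 0.5 of a peak. As a ratio, 11.6, it ran from 8.41 to 18.9 with each library left out. The loss odds ratio stayed above 1 in the alternatives run, from 1.52 to 3.46.

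Near Cdx2 peaks, the odds ratio of higher genes lost its call at 1 kb (0.818), 50 kb (0.947) and in regions accessible in both Wt libraries (0.893). Matched on mean count, it kept its call there (0.668, 0.806 and 0.745). That of lower genes (1.48) kept its call in the alternatives run. It was 1.29 (1.06 to 1.56) at 1 kb, 1.32 at 50 kb and 1.22 (1.04 to 1.43) in regions accessible in both Wt libraries. With Cdx2 peaks of -log10 q of 5 or more it was 1.54. The set test p of 0.0478 rose to 0.220 at 1 kb, 0.226 at 50 kb, 0.384 in accessible regions, 0.366 with a correlation of 0.05 and 0.118 with ranks. Near lost regions, the odds ratio of lower genes turned to 0.919 at 50 kb and 0.812 with stricter ATAC peaks, or 0.895 and 0.790 matched. That of higher genes (0.874) turned to 1.15 and 1.06, but matched it kept its call at 0.758 and 0.697. Leaving out each ATAC library gave 0.965 to 1.19 for lower and 0.876 to 0.940 for higher genes, and 0.949 to 1.18 and 0.653 to 0.740 matched. The value for lower genes turned without DKO replicate 2 in both forms, and its matched call was lost without DKO replicate 1 (1.09). The value for higher genes lost its unmatched call without DKO replicate 2, Wt replicate 1 or Wt replicate 2, and kept its matched call. Near gained regions, the odds ratio of lower genes was 1.04 at 1 kb, 1.04 at 50 kb and 0.964 with stricter ATAC peaks, or 1.05, 1.04 and 0.940 matched. That of higher genes ran from 0.837 to 0.919 with each ATAC library left out, passing without DKO replicate 1, DKO replicate 2 or Wt replicate 2. Matched, it ran from 0.865 to 0.988, passing without DKO replicate 1, and was 1.10 with stricter ATAC peaks. The cause of these moves was not tested. Of 40 alternative tests of the called gene lists, 34 kept the call and 6 lost it. Of 64 tests of the other lists, 62 stayed without a call and 2 gained one, and none of the called lists turned, while 7 directions turned in lists that were not called. Not run, for want of gene-level library values or a genome, were the estimated correlation, fry, the library alternatives for gene lists and named genes, and the motif windows. With 200 simulated transcripts changed, edgeR recovered 0% of the 4-fold changes at the observed dispersion of 0.441, against 100% at 0.05. Far more transcripts were called in the data, and the adjusted p depends on the share that change. These rates therefore do not give the power of the test on the data. The effect of depth was not tested.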

Other observations

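The gene families and the split of Cdx2 peaks below were chosen after seeing the data. Grouping protein-coding genes of the authors' deposited table by the letters that open their symbols, with 4 biotypes, gave 270 families of at least 8 genes. Collagen genes, Col, were lower in 21 and higher in 1 of 34 by the authors' deposited table (median log2 fold change -2.53, cameraPR adjusted p = 6.90e-10). Immunoglobulin variable genes were lower in 55 and higher in 0 of 96 in the authors' deposited table (adjusted p = 1.07e-06). Carboxylesterases, Ces, were lower in 8 and higher in 2 of 13 (adjusted p = 1.47e-07), hydroxysteroid dehydrogenases, Hsd, lower in 6 and higher in 2 of 14 (adjusted p = 8.70e-06), and cytochromes P450, Cyp, lower in 17 and higher in 5 of 46 (adjusted p = 0.0223), counted from the authors' deposited table. Ly genes rose, 8 higher and 1 lower of 21 in the authors' deposited table (adjusted p = 1.07e-06), and Apol genes were lower in 5 and higher in 3 of 12 (adjusted p = 0.0329).

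Cdx2 peaks were split into 10 deciles of fold enrichment. In the lowest decile, 50.8% and 54.1% lay inside an ATAC peak of Wt replicates 1 and 2, against 32.4% and 34.7% in the highest decile. The share within 1 kb of a gene end went from 31.4% to 7.06%. Of 5100 peaks, 2799 lay outside the ATAC peaks of both Wt lists, and whether these are sites of Cdx2 binding was not tested. Among 986 genes whose only Cdx2 peaks within 10 kb were of that kind, 28.1% were lower in the authors' deposited table, against 22.3% of 981 genes whose only such peaks lay inside a Wt ATAC peak (odds ratio 1.36, Fisher's exact p = 0.00362) and 18.6% of genes with none.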
